A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

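RNA was sequenced from Saccharomyces cerevisiae of a CEN.PK prototrophic background in 3 genotypes: wild type (WT), a strain lacking PAH1 (pah1Δ) and a strain lacking DGK1 (dgk1Δ). Each genotype had 3 libraries, 9 in all. Per the labels' protocols, cells grew to log phase in a defined medium with 2% glucose and were frozen before RNA extraction, and libraries were made from 2 µg of total RNA by poly(A) selection and random-primed cDNA. The protocol names no step that marks the strand, so reads from overlapping or antisense genes cannot be told apart, and such genes are reported as uncertain. The labels number the replicates 1 to 3 but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

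The deposited table held whole-number read counts per gene, 1 column per library, with no normalization per the file headers and the values. It also held FPKM values, which the authors had computed: each equalled the count divided by the exonic gene size and by a library total that lay 0.0158% to 0.0225% above the sum of that library's count column. Per the submitters' processing notes, HISAT2 version 2.2.1, HTSeq version 0.6.1 and the genome build R64 were used. The annotation release, the strand setting and the treatment of reads matching more than 1 place are not given in the sources used here. Genes with near-identical copies, such as many ribosomal protein, histone, MAL and IMD genes, may therefore share or lose reads. Positions are those of the deposited table; 6045 of its 7122 gene identifiers matched the reference annotation of the same build, and 6033 of these had the same start and end. In all, 4 lines of the table were empty and were not used, and 321 genes had a count of 0 in every library. No columns of other samples were present (0 columns not used).

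Total counts over genes ranged from 9205454 to 12795803 per library. A count of 0 allows up to 3 counts in a library, and this floor and the exact 95% intervals given for ratios of counts cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared by a chi-square statistic per degree of freedom over genes: it ranged from 3.61 to 55.1 between libraries of 1 group, so no pair agreed within sampling noise and all 9 libraries were counted.

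Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (6150 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per genotype was fitted over all 9 libraries (robust estimation, 6 residual degrees of freedom, common biological coefficient of variation 0.106). The 3 contrasts were pah1Δ minus WT, dgk1Δ minus WT and pah1Δ minus dgk1Δ. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 (edgeR's quasi-likelihood test), with no minimum fold. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled by library size and TMM factor, given as mean ± SD (n = 3).

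The design, the alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined, from textbook knowledge of yeast. MLP1 was taken out of the cell wall list after the table had been seen but before any list was tested, because the entry was a mistake. Of the list entries, 4 were matched by a synonym and 1 was not matched. Lists were tested with camera (limma 3.58.1; preset correlation 0.01, two-sided), adjusted over the 30 lists within each contrast. Camera was repeated with an estimated correlation, and fry was run as an alternative. For the contrasts with WT, named genes are both deleted genes, the annotated neighbour on either side of the deleted one, and the 10 largest rises and 10 largest falls. Those needed a standard symbol, a call, a mean CPM of at least 10 and no overlap between the groups' libraries. All members of the list with an inositol-responsive element were named, with up to 4 members of each other called list and up to 2 of each list not called, by smallest adjusted p. For pah1Δ against dgk1Δ the 5 largest rises and falls were named. Genes outside this rule are said to have been chosen after their values were seen.

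Alternatives were RLE size factors, library size only, no filter, a mean CPM of at least 10, only the 2 groups compared, a replicate block, leaving out each replicate, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold of at least 2, and an adjusted p under 0.01. A median per chromosome was computed, with a difference of over 0.2 (log2) from the median of all genes as the planned mark of a copy-number change. Chosen after seeing the data were a scan for runs of shifted genes along each chromosome (genes with a mean CPM of at least 10, runs of at least 15 genes, 100 shuffles of gene order), fits without the genes of the segments it found, a comparison of the segments with other genes in the same of 20 bins of expression, a loess correction of each library for gene length (span 0.5), a fit without WT replicate 1 and pah1Δ replicate 2, tests of genes within 30 kb of a chromosome end, and camera over 93 KEGG pathways of the deposited annotation. Unchanged groups against the shared WT libraries were simulated in 100 draws.

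The steps were tested on simulated counts. With 200 of 6150 genes changed, the simulation of pah1Δ against WT recovered 58.2% of genes changed by a log2 of 0.5, 92.3% at 1 and 100% at 2, with 7 false calls. For dgk1Δ against WT the shares were 62.1%, 89.6% and 100%, with 11 false calls, and for pah1Δ against dgk1Δ 45.5%, 93.8% and 100%, with 7. In the simulation of pah1Δ against WT, camera called 0 of 100 unchanged lists and 4 of 4 lists shifted by 0.5 (6092 genes). These were random lists of genes drawn independently of each other. The simulation therefore cannot show how often camera calls unchanged lists of genes that vary together. The scan found the 1 planted run of 40 genes and 0 others (5304 genes). Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.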

Results

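Poly(A) RNA was measured in log-phase budding yeast of 3 genotypes, WT, pah1Δ and dgk1Δ, with 3 libraries each. PAH1 encodes the phosphatidate phosphatase that makes diacylglycerol, and DGK1 encodes the diacylglycerol kinase that turns diacylglycerol back into phosphatidate. The comparisons ask how gene expression differs between the deletion strains and WT under ordinary growth. All 3 dgk1Δ libraries also had higher RNA over 2 chromosome segments, described below. Differences in dgk1Δ therefore cannot be assigned to the loss of DGK1 apart from these segments. Each library held 9205454 to 12795803 counts over genes. WT replicate 1 stood apart from the other WT libraries (chi-square per degree of freedom 55.1 and 41.0, against 3.61 between WT replicates 2 and 3). Its log2 deviation from them fell with gene length (Spearman correlation across 5304 genes -0.745), as did that of pah1Δ replicate 2 (-0.682), while those of WT replicates 2 and 3 rose with length (0.693 and 0.605). In the other libraries it was 0.33 and 0.639 (pah1Δ replicates 1 and 3) and -0.138, 0.537 and -0.429 (dgk1Δ replicates 1 to 3).

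The deleted genes matched the labels in all 9 libraries. PAH1 (YMR165C, chromosome XIII, 590040 to 592628, build R64) had 0 counts in each pah1Δ library, against 454 to 535 in WT and 507 to 722 in dgk1Δ. Its level was 49.1 ± 6.75 CPM in WT and 53.5 ± 3.16 CPM in dgk1Δ (SD, n = 3), at least 174-fold lower in pah1Δ than in WT and at least 189-fold lower than in dgk1Δ, against a floor of 3 counts per library (mean 0.283 CPM). DGK1 (YOR311C, chromosome XV, 899056 to 899928) had 1, 2 and 1 counts in the dgk1Δ libraries, against 1030 to 1502 in WT and 1038 to 1267 in pah1Δ. The ratio of WT to dgk1Δ, scaled by total counts, was 939 (exact 95% interval 367 to 3450). DGK1 did not pass the test in pah1Δ (log2 fold change -0.13, SE 0.0813, edgeR adjusted p = 0.257), nor PAH1 in dgk1Δ (0.12, SE 0.116, 0.856). The neighbours of PAH1, MSS11 and YMR166C, gave 0.04 (0.893) and -0.12 (0.359) in pah1Δ. The neighbours of DGK1, NOP58 (overlapping YOR309C) and RPL20B, gave -0.12 (0.692) and -0.06 (0.927) in dgk1Δ.

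**Figure D1:**
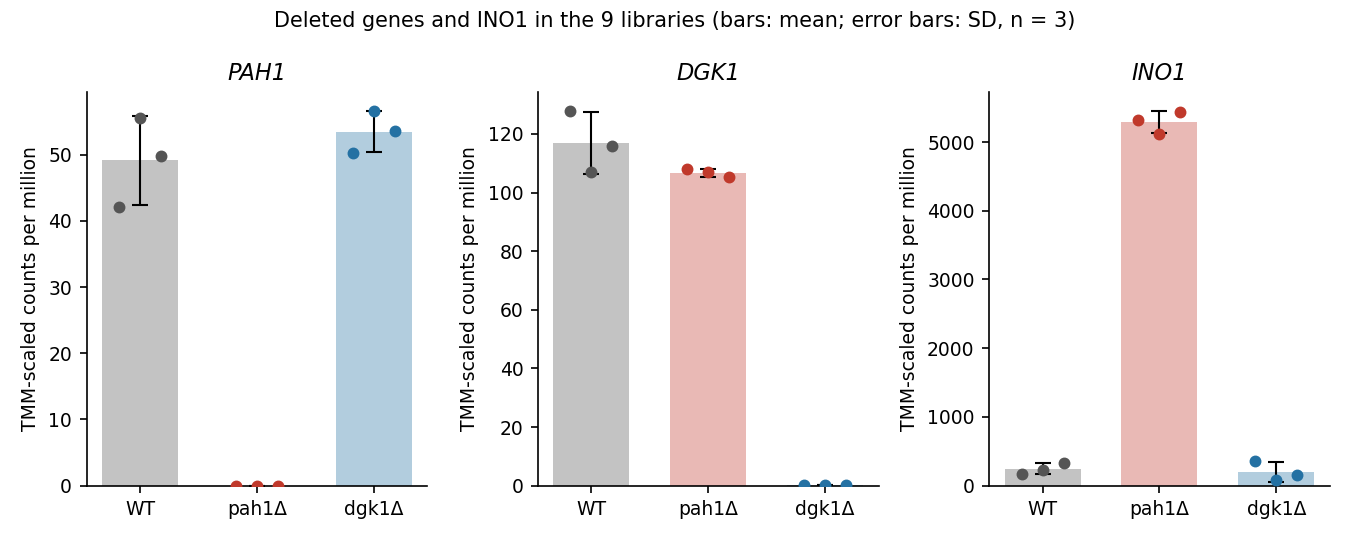
TMM-scaled CPM of PAH1, DGK1 and INO1 in the 9 libraries (points), with the group mean (bar) and SD (error bar, n = 3) on linear axes from 0. PAH1 is at 0 in pah1Δ, DGK1 at 1 or 2 counts in dgk1Δ, and INO1 lies at 5293 ± 162 CPM in pah1Δ against 245.9 ± 83.1 in WT.

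In pah1Δ against WT, INO1, which encodes the inositol-3-phosphate synthase of phosphatidylinositol synthesis, rose most among the named genes (log2 fold change 4.43, SE 0.477, edgeR adjusted p = 6.8e-05). Its level was 5293 ± 162 CPM in pah1Δ and 245.9 ± 83.1 in WT (SD, n = 3). Of the 19 genes listed with an inositol-responsive promoter element, 5 rose and 2 fell, also when adjusted over the list alone. Besides INO1, the phospholipid methyltransferase OPI3 rose by 1.05, the inositol transporter ITR1 by 0.48, INO4, a subunit of the activator of these promoters, by 0.40, and the methyltransferase CHO2 by 0.31. The choline transporter HNM1 fell by 0.39 and PCT1, the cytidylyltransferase of choline phosphate, fell by 0.37. PSD1 (0.35, overlapping YNL170W), CHO1 (0.31), EPT1 (0.15), CKI1 (0.14), PSD2 (0.13), EKI1 (0.11), OPI1 (0.01), CDS1 (-0.02), CPT1 (-0.04), INO2 (-0.05), ECT1 (-0.10) and PIS1 (-0.23) did not pass. The list as a whole had a median of 0.13 and was not called (camera adjusted p = 0.377); the median was 0.03 and 0.07 without WT replicate 1 and pah1Δ replicate 1, and 0.21 with library size only. CHO2 lost its call when 1 library was left out in 5 fits (WT replicates 2 and 3 and each pah1Δ library; adjusted p 0.0736 to 0.103) and with a replicate block, INO4 in 4 (WT replicates 2 and 3, pah1Δ 1 and 2; 0.0529 to 0.0624) and ITR1 in 3 (WT 2, pah1Δ 1 and 3; 0.0701 to 0.0849). Over all alternatives the adjusted p ranged from 0.015 to 0.103, 0.000248 to 0.0624 and 0.00577 to 0.0849, respectively.

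**Figure D2:**
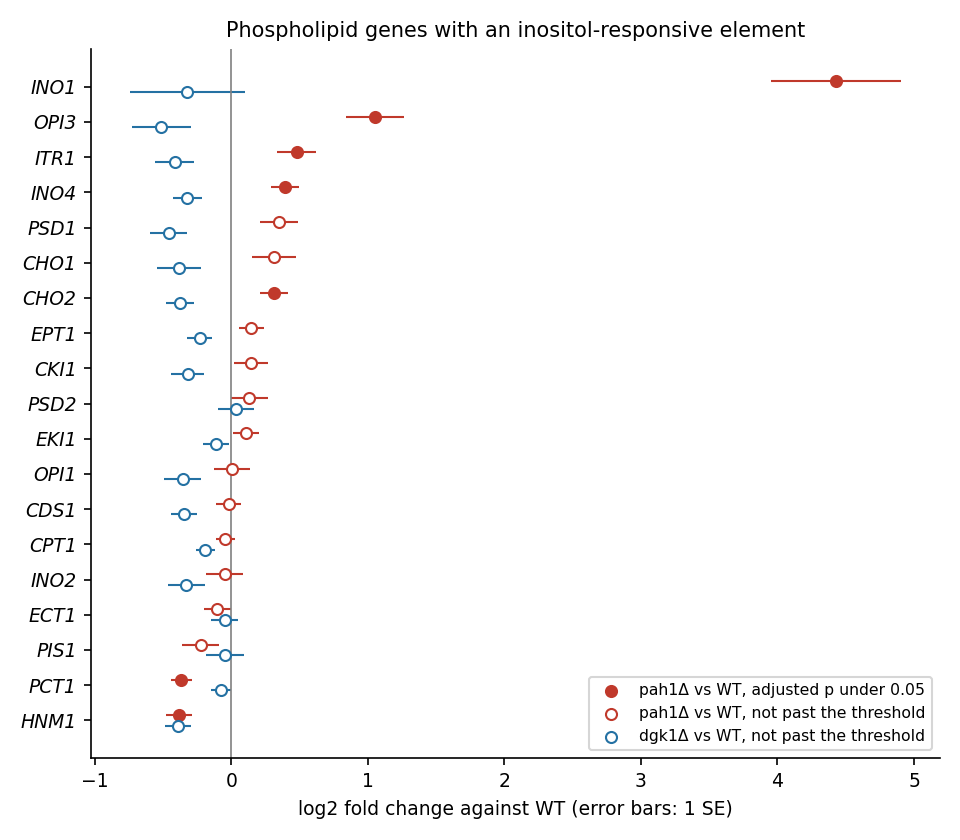
Log2 fold changes against WT (x axis, with 1 SE) of the 19 phospholipid genes with an inositol-responsive element, in pah1Δ (red) and dgk1Δ (blue); filled points passed an adjusted p of 0.05. INO1 lies at 4.43 in pah1Δ and at -0.32 in dgk1Δ.

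Most genes of the general stress, stationary-phase, cell wall integrity and beta-oxidation lists rose in pah1Δ. Of 37 general stress genes (targets of Msn2 and Msn4), 35 rose and 0 fell, with a median of 1.51: YGP1, a secreted glycoprotein, rose by 3.74 (SE 0.13), the hexokinase HXK1 by 2.63 (overlapping YFR052C-A), the small heat shock protein HSP42 by 2.04 and the glucokinase GLK1 by 1.70 (overlapping YCL042W). Adjusted over the list alone, 35 were higher and 1 lower. Of 16 stationary-phase genes 13 rose (14 adjusted over the list alone), median 1.43, among them RTC3 (2.18), FMP16 (2.37) and RTS3 (1.45). Of 21 cell wall integrity genes (targets of Slt2 and Rlm1), 16 rose and 1 fell, also when adjusted over the list alone, with a median of 1.22; the cell wall protein PIR3 rose by 3.40, YLR194C by 1.90, the protease gene YPS3 by 1.83 (overlapping YLR120W-A) and the kinase gene KDX1 by 1.497. Of 20 genes of peroxisomal beta-oxidation 12 rose (13 adjusted over the list alone), median 0.53, including the acyl-CoA oxidase POX1 (2.26), the thiolase POT1 (2.13), SPS19 (1.60, overlapping YNL203C) and the carnitine acetyltransferase CAT2 (0.90). Camera gave adjusted p of 9.91e-56, 3.73e-15, 5.41e-27 and 4.67e-07 for these 4 lists, and they were also called with an estimated correlation (adjusted p = 0.00154, 0.00192, 0.0316 and 0.0118).

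Most ribosome biogenesis, cytosolic ribosomal protein and histone genes fell in pah1Δ, and few mitochondrial ribosome genes did. Of 52 ribosome biogenesis genes 48 fell and 0 rose (51 lower adjusted over the list alone), median -0.42, among them the helicase gene DBP2 (-0.97), RRP5 (-0.60), ERB1 (-0.52) and UTP8 (-0.44). Camera called this list both ways (adjusted p = 1.34e-17; 0.0483 with an estimated correlation). Of 138 cytosolic ribosomal protein genes 90 fell and 0 rose (122 lower adjusted over the list alone), median -0.44, including RPL18B (-0.77), RPL9A (-0.76), RPS26B (-0.68) and RPL28 (-0.45, overlapping YGL102C). Most are near-identical pairs that can share reads. The call (adjusted p = 4e-17) was lost with an estimated correlation (adjusted p = 0.397 with an estimated correlation). The list's median against the WT mean was 0.44, -0.28 and -0.15 in WT replicates 1 to 3 and -0.48, -0.25 and -0.54 in pah1Δ replicates 1 to 3. Without WT replicate 1 the list's log2 fold change had a median of -0.28 (camera adjusted p = 3.47e-11). Of 10 histone genes 7 fell (8 adjusted over the list alone), median -0.42, among them HHT1 (-0.61), HTA2 (-0.61), HTB2 (-0.58) and HHF1 (-0.46; camera adjusted p = 0.00179, adjusted p = 0.397 with an estimated correlation). The histone median was 0.32 in WT replicate 1. Of 66 mitochondrial ribosome genes 7 fell and 1, MRP8, rose by 0.92 (0 lower and 1 higher adjusted over the list alone). MRPS9 (-0.31), RSM26 (-0.39) and MRPL35 (-0.32) fell, but each lost its call without pah1Δ replicate 1 or 3, MRPL35 also without WT replicate 3 (adjusted p up to 0.0708, 0.09 and 0.0805); library size only and only the 2 groups compared ended all 3 calls, and FPKM that of MRPL35. The call of this list (0.00504) was lost with an estimated correlation (adjusted p = 0.643 with an estimated correlation), without WT replicate 1, in which its median was 0.37 (camera adjusted p = 0.329), without pah1Δ replicate 3 (0.0837), and with fry (0.251). Its median of -0.16 was -0.04, -0.09 and -0.24 without WT replicate 1, pah1Δ replicate 3 and pah1Δ replicate 2, respectively, and -0.06 with library size only.

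Metal, phosphate and nutrient genes changed in both directions in pah1Δ. Of 15 genes of the zinc regulon (targets of Zap1) 10 fell and 1 rose (10 lower and 2 higher adjusted over the list alone), median -0.57. ZPS1, a cell surface protein, had the largest fall of all named genes apart from PAH1 (-4.44, SE 0.525, edgeR adjusted p = 0.000129), followed by the zinc transporter ZRT1 (-2.87) and the alcohol dehydrogenase ADH4 (-2.86), and the vacuolar zinc transporter ZRC1 fell by 0.57. Of 23 genes of the iron regulon 11 rose and 1 fell (13 and 2 adjusted over the list alone), median 0.23: TIS11, which binds mRNAs of iron-requiring proteins, rose by 3.10, the siderophore transporter ARN1 by 1.26, the haem oxygenase HMX1 by 1.03 and CCC2 by 0.78 (overlapping YDR269C and YDR271C). Of 19 genes of the phosphate regulon 8 rose and 1 fell, also when adjusted over the list alone, median 0.31, including PHM8 (1.92), PHM7 (1.61), the phosphate transporter PHO84 (1.12) and the glycerophosphoinositol transporter GIT1 (1.07). Of 44 amino acid synthesis genes (targets of Gcn4) 24 fell and 1, SNZ1, rose by 0.98 (29 and 2 adjusted over the list alone), median -0.25: ARG3 fell by 1.25, LEU9 by 0.88 (overlapping YOR108C-A) and ARG8 by 0.77. Of 30 methionine and sulfur assimilation genes 12 fell and 3 rose (14 and 4 adjusted over the list alone), median -0.20, among them MET16 (-0.65), SAM3 (-0.58), MET1 (-0.54) and MET14 (-0.49). Camera called these 5 lists (adjusted p = 1.47e-06, 0.000526, 0.000572, 4.11e-08 and 0.00416), and all 5 calls were lost with an estimated correlation (adjusted p = 0.0915, 0.127, 0.119, 0.127 and 0.296 with an estimated correlation). With library size only the median of the Gcn4 list was -0.16 and that of the methionine list -0.11.

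Some genes of protein folding, autophagy, glucose repression and respiration rose in pah1Δ. Of 24 genes of the unfolded protein response 13 rose (17 adjusted over the list alone), median 0.42, among them the endoplasmic reticulum chaperone KAR2 (1.05), the oxidase ERO1 (0.89), LHS1 (0.59) and SIL1 (0.58). Of 24 Hsf1 chaperone genes 16 rose (18 higher and 1 lower adjusted over the list alone), median 0.36, including HSP42, HSP104 (1.47), HSP82 (1.41) and BTN2 (1.31). Of 22 autophagy genes 11 rose, also when adjusted over the list alone, median 0.42, among them ATG8 (1.22), ATG17 (0.84), ATG19 (0.82) and ATG3 (0.67). Of 23 glucose-repressed genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), median 0.28: MAL32 (1.68, with a near-identical copy), the hexose transporter HXT5 (1.68) and IDP2 (1.22) rose, and the invertase gene SUC2 fell by 0.57. Of 37 respiratory chain genes 9 rose, also when adjusted over the list alone, median 0.17, including SDH4 (0.64), SDH2 (0.55), SDH1 (0.54) and NDE1 (0.43). Camera called these 5 lists (adjusted p = 2.02e-05, 3.12e-10, 0.000303, 0.0233 and 0.0277), and all 5 calls were lost with an estimated correlation (adjusted p = 0.0915, 0.0915, 0.142, 0.163 and 0.605 with an estimated correlation). The glucose-repressed list was also not called once the length trend was removed (0.117) or with a mean CPM of at least 10, nor the respiratory list without WT replicate 2 or 3 or pah1Δ replicate 2 (adjusted p 0.0582 to 0.186). Without pah1Δ replicate 2 the medians of these lists were 0.17 and 0.11, and with library size only the respiratory median was 0.26.

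Most MATa-specific genes fell and some MATalpha-specific genes rose in pah1Δ. Of 7 MATa-specific genes 6 fell, also when adjusted over the list alone, median -0.72, among them the pheromone genes MFA2 (-1.03) and MFA1 (-0.85), the receptor STE2 (-0.89) and the exporter STE6 (-0.72; limma on FPKM gave STE6 an adjusted p of up to 0.0534). Of 4 MATalpha-specific genes 2 rose, also when adjusted over the list alone: the pheromone gene MF(ALPHA)1 by 1.86 and the receptor STE3 by 1.41 (overlapping YKL177W), while MF(ALPHA)2 (0.37) and SAG1 (0.05) did not pass. Camera called both lists (adjusted p = 0.000403 and 0.015), and both calls were lost with an estimated correlation (adjusted p = 0.0686 and 0.114 with an estimated correlation). The MATa median was 0.40 in WT replicate 1, -0.36 in replicate 2 and -0.03 in replicate 3, and the MATalpha call ended with the length trend removed (0.0574).

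The other lists had few called members, changes in both directions or no call by camera in pah1Δ. Of 18 genes of fatty acid synthesis and activation 3 fell, also when adjusted over the list alone, median -0.12: the acyl-CoA synthetase genes FAA4 (-1.10) and FAA3 (-0.74) and the elongase gene ELO3 (-0.26), with HFA1 at -0.36 (edgeR adjusted p = 0.0503). ELO3 lost its call without WT replicate 3 or pah1Δ replicate 1 or 2 (adjusted p 0.0508 to 0.0669), with library size only, with only the 2 groups and on FPKM. Of 28 nuclear pore genes 2 fell (0 adjusted over the list alone), NUP100 (-0.45) and NUP49 (-0.24), with NUP145 at -0.25 and NUP157 at -0.23. NUP100 and NUP49 both lost their calls without WT replicate 3 or pah1Δ replicate 1, NUP100 also without pah1Δ replicate 2 (up to 0.0596 and 0.0704), both with library size only and on FPKM, and NUP49 with only the 2 groups or a replicate block. In WT replicate 1 the medians of these lists were -0.25 and -0.27. Camera called both (adjusted p = 0.0496 and 0.0347), and both calls were lost with an estimated correlation (adjusted p = 0.365 and 0.605 with an estimated correlation) and without WT replicate 2 or 3 or pah1Δ replicate 2 (0.0781 to 0.143 and 0.0825 to 0.143). Both calls also ended with the length trend removed (0.142 and 0.0519; medians -0.04 and -0.09), with library size only (0.077 and 0.0663; medians -0.04 and -0.06) and with a mean CPM of at least 10. The fatty acid call ended without segment genes (0.0758) and with only the 2 groups, and the nuclear pore call with fry (0.154). The fatty acid median was -0.07 without pah1Δ replicate 2, and the nuclear pore median of -0.14 was -0.23 without WT replicate 1 and -0.09 without WT replicate 2 or pah1Δ replicate 2. Camera called none of the following lists, though fry called all but glycolysis and camera the meiosis list without pah1Δ replicate 1. Of 28 phosphatidate and neutral lipid genes 7 rose and 2 fell, also when adjusted over the list alone, including ICT1 (1.23) and the lipid droplet protein PET10 (0.58; list 0.247). Of 25 sphingolipid genes 11 rose and 3 fell (12 and 4 adjusted over the list alone), including YPC1 (0.74) and ORM2 (0.72; list 0.2). Of 25 ergosterol genes 6 rose, also when adjusted over the list alone, with ERG27 at 0.44 (overlapping YLR101C) and ERG20 at 0.34 (list 0.356). Of 16 genes of the tricarboxylic acid cycle 7 rose and 1 fell (7 and 2 adjusted over the list alone), LSC2 (0.56) and ACO1 (-0.46) among them (list 0.2). Of 19 glycolysis genes 4 rose, including TDH1 (1.32) and ENO1 (0.63), and 7 fell (4 and 11 adjusted over the list alone; list 0.208). Of 21 S-phase genes 4 rose, also when adjusted over the list alone, including PCL1 (0.86) and CLN1 (0.78; list 0.553). Of 18 meiosis genes 7 rose, also when adjusted over the list alone, median 0.37, including DMC1 (1.15) and HOP1 (1.14, camera adjusted p of the list 0.0768).

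**Figure D3:**
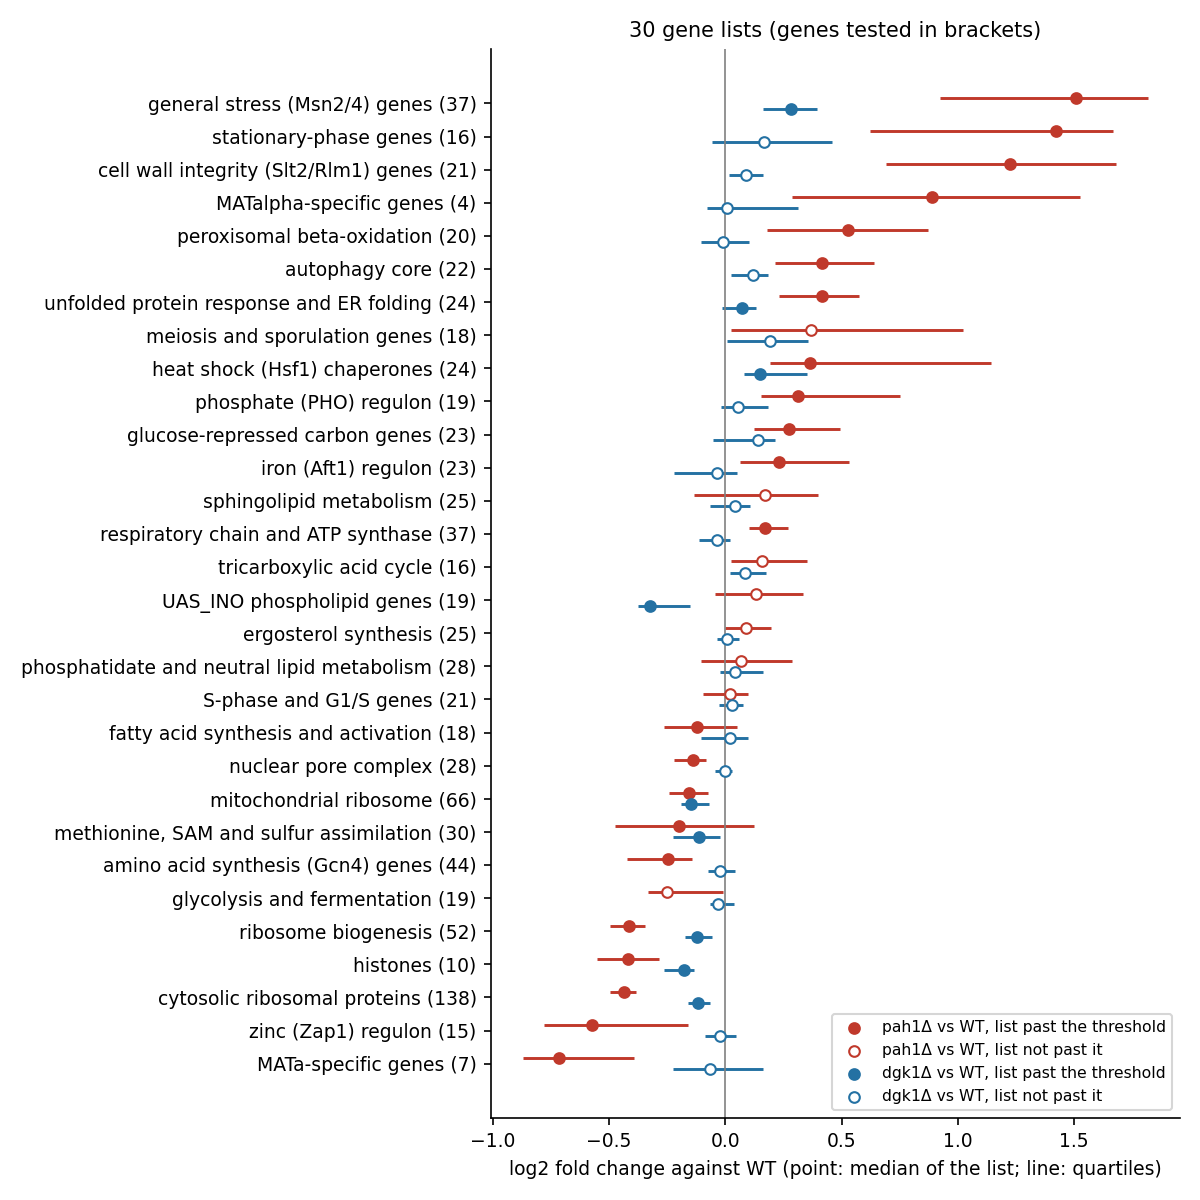
Median (point) and quartiles (line) of the log2 fold changes against WT (x axis) of the 30 gene lists, in pah1Δ (red) and dgk1Δ (blue); filled points passed camera with the preset correlation at an adjusted p of 0.05. General stress genes have the highest median in pah1Δ, 1.51, and MATa-specific genes the lowest, -0.72.

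Other genes with large rises in pah1Δ were TMA10 (log2 fold change 3.61), the transaldolase NQM1 (3.24), the membrane protein HSP12 (3.06), the stress protein DDR2 (2.76) and GPG1 (2.64). Large falls were those of ALG8, a glucosyltransferase of N-glycan assembly (-1.71), the uridine permease FUI1 (-1.61), ATO3 (-1.49), WSC4 (-1.399), the phospholipase PLB2 (-1.22) and the ammonium permease MEP2 (-1.20). In all, 1023 genes were higher and 775 lower among 6150 tested. The split of the calls into higher and lower depended on the scaling: with library size only 1343 were higher and 480 lower, and on log2(FPKM + 1) 1329 and 462, so that the higher share went from 56.9% to 73.7% and 74.2%. Without WT replicate 1 the lower calls numbered 1172, and without pah1Δ replicate 1 they numbered 447.

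In dgk1Δ against WT, MUP1, the high-affinity methionine permease, fell by 1.41 (log2, SE 0.103, edgeR adjusted p = 2.38e-05), the S-adenosylmethionine permease SAM3 by 1.13 (SE 0.0746, 1.56e-05), the homocysteine methyltransferase MHT1 by 0.75 and the S-methylmethionine permease MMP1 by 0.69. Of 30 methionine and sulfur assimilation genes 5 fell and 0 rose (7 and 1 adjusted over the list alone), median -0.11. Camera called this list (adjusted p = 3.41e-10), and the call was lost with an estimated correlation (adjusted p = 0.216 with an estimated correlation). Other large falls were those of RPS14B (-0.91), NIT1 (-0.79), the oligopeptide transporter OPT1 (-0.76), STR3, a cystathionine lyase (-0.72), ARR1 (-0.57) and the sulfatase BDS1 (-0.54). ARR1 lost its call without dgk1Δ replicate 1 or 2 (adjusted p 0.0576 and 0.0713) and BDS1 without dgk1Δ replicate 2 (0.0555) and on FPKM.

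No phospholipid gene with an inositol-responsive element passed edgeR's test over all genes in dgk1Δ. Of 19, edgeR called 0 over all genes, limma-voom 0 and DESeq2 4, while 13 were lower at an unadjusted p under 0.05 and 6 adjusted over the list alone. The median was -0.32, and the values included OPI3 (-0.51), PSD1 (-0.46, overlapping YNL170W), ITR1 (-0.42), HNM1 (-0.39), CHO1 (-0.38), CHO2 (-0.38) and INO1 (-0.32, SE 0.421). The remaining values were OPI1 -0.36, CDS1 -0.34, INO2 -0.33, INO4 -0.32, CKI1 -0.32, EPT1 -0.23, CPT1 -0.19, EKI1 -0.11, PCT1 -0.07, ECT1 -0.05, PIS1 -0.05 and PSD2 0.03. Camera called the list (adjusted p = 2.91e-07), and the call was lost with an estimated correlation (adjusted p = 0.528 with an estimated correlation) and with fry (0.0644). The list's median against the WT mean was -0.08 in dgk1Δ replicate 1, -0.43 in replicate 2 and -0.39 in replicate 3, against -0.06, -0.06 and 0.10 in WT replicates 1 to 3. INO1 lay at 355.2 CPM in dgk1Δ replicate 1, above each WT library (172.0 to 335.9), and at 80.41 and 154.0 in replicates 2 and 3.

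Few stress genes passed the test in dgk1Δ. Of 37 general stress genes 4 rose (8 adjusted over the list alone), median 0.28: GLK1 (1.42, overlapping YCL042W, on the chromosome III segment described next), HXK1 (0.81, overlapping YFR052C-A), the nicotinamidase PNC1 (0.61) and HSP42 (0.40). PNC1 and HSP42 lost their calls when WT replicate 2 or 3 or any dgk1Δ library was left out (adjusted p 0.068 to 0.16 and 0.0511 to 0.178). HXK1 lost its call with only the 2 groups compared (0.0509), and so did HSP42, also with a replicate block. Of 24 Hsf1 chaperone genes 1, HSP42, rose (9 adjusted over the list alone), median 0.15, with HSP104 at 0.40, HSP82 at 0.36 and CPR6 at 0.35 (overlapping YLR217W). Camera called both lists (adjusted p = 3.41e-10 and 9.22e-05), and both calls were lost with an estimated correlation (adjusted p = 0.154 and 0.528 with an estimated correlation). The Hsf1 median was 0.10 without WT replicate 3. Of 52 ribosome biogenesis genes edgeR called 0 (DESeq2 1, limma-voom 0; 11 lower at an unadjusted p under 0.05), median -0.12, with NOC4 (-0.28), NOP4 (-0.26, overlapping YPL044C), NOG2 (-0.25, overlapping snR191) and NOC3 (-0.22); the list was called (5.9e-06) but not with an estimated correlation (adjusted p = 0.528 with an estimated correlation). Of 138 ribosomal protein genes 1, RPS14B, fell, also when adjusted over the list alone, median -0.12, with RPL22B (-0.33), RPL9B (-0.25) and RPL26A (-0.24). Of 66 mitochondrial ribosome genes edgeR, DESeq2 and limma-voom called 0 (4 lower at an unadjusted p under 0.05), median -0.15, with MRP20 (-0.26), MRPS9 (-0.23), MRPL22 (-0.20) and MRP4 (-0.19, overlapping YHL005C). Of 10 histone genes the same tools called 0 (4 lower at an unadjusted p under 0.05), median -0.18, with HTB1 (-0.39), HTA1 (-0.38), HHT1 (-0.27) and HTZ1 (-0.21). Camera called these 3 lists (9.22e-05, 0.000129 and 0.00324). The calls were lost with an estimated correlation (adjusted p = 0.851, 0.781 and 0.718 with an estimated correlation) and without WT replicate 1, in which the lists' medians were 0.44, 0.37 and 0.32 (adjusted p = 0.47, 0.715 and 0.184). Their medians were then 0.05, -0.01 and -0.08. The ribosomal protein median was also -0.21, -0.18 and -0.07 without WT replicate 2, WT replicate 3 and dgk1Δ replicate 2, and -0.06 with the length trend removed. Fry called none of the 3 lists (0.629, 0.526 and 0.269).

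Most higher genes in dgk1Δ lay in 2 chromosome segments. Of the 101 higher calls 84 (83.2%) were among the 102 tested genes (1.66% of all) of a stretch of chromosome III from CHA1 to KCC4 (15798 to 82275, 66.5 kb) and of chromosome IX from YIL014C-A to YIR042C (325212 to 435983, 110.8 kb, holding the centromere at 355629 to 355745). All 41 tested genes of the first had fold changes above 0, with 33 called and a median of 1.03 (quartiles 0.88 and 1.09); so had all 61 of the second, with 51 called and a median of 0.92 (0.81 and 1.03). Among called genes with a standard symbol, a mean CPM of at least 10 and groups that do not overlap, the 10 largest rises all lay in them: the transcription factor gene MGA2 (1.43), GLK1 (1.42), the mating gene FUS1 (1.399), the glutathione transferase GTT1 (1.33), the glutaredoxin GRX1 (1.198), the splicing gene MSL1 (1.19), DCG1 (1.17), MGR1 (1.17), ATG22 (1.16) and the allantoin permease DAL4 (1.14). The segment medians lay between 0.86 and 1.01 in the 3 dgk1Δ libraries and between -0.09 and 0.14 in the other 6. No shuffle of gene order out of 100 gave a run as large (0 of 100), and 0 segments were called in pah1Δ against WT. The planned comparison of whole chromosomes did not pass its mark of 0.2 (largest difference 0.0498).

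**Figure D4:**
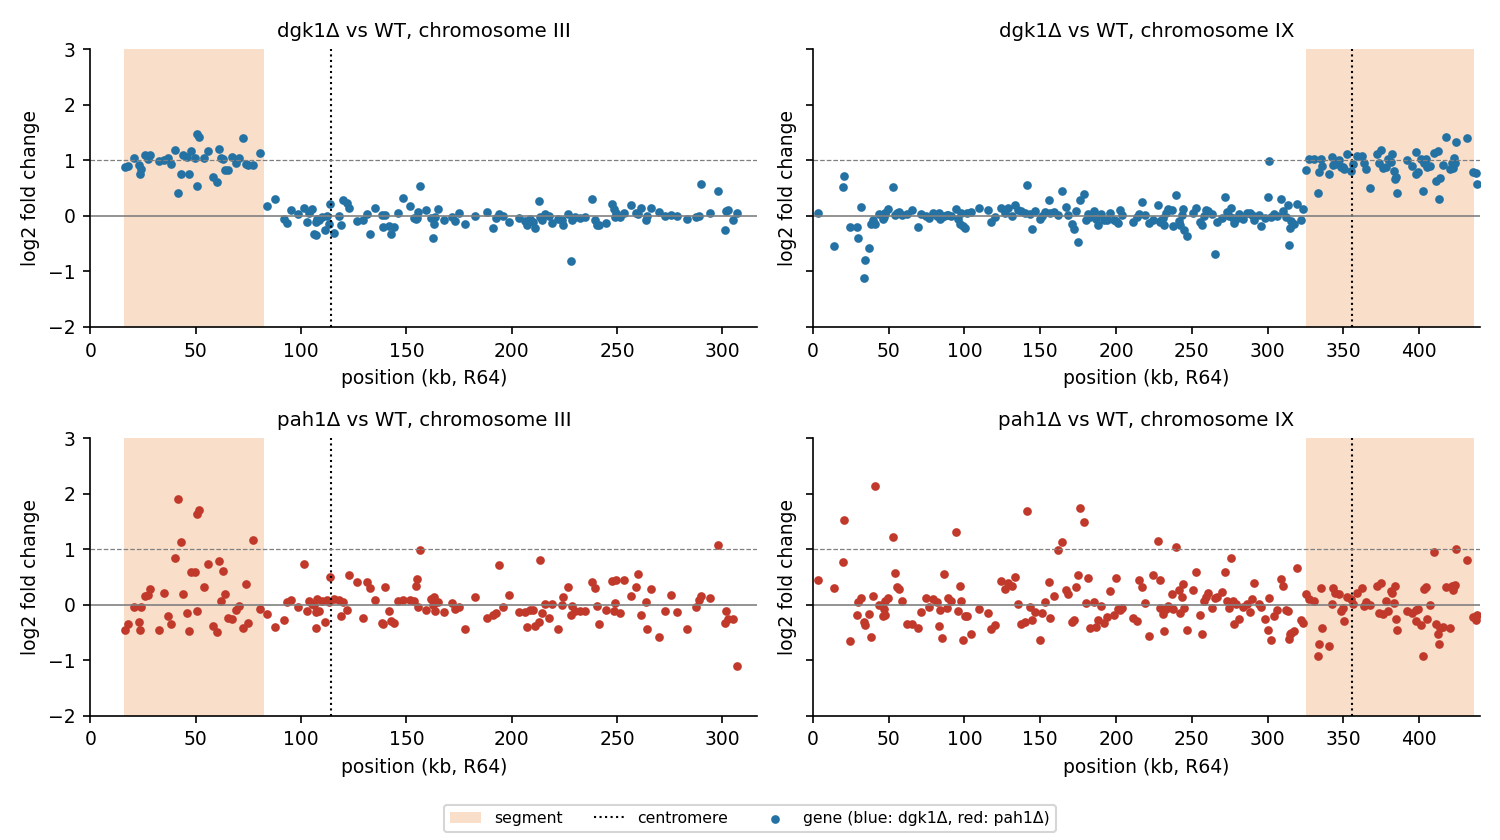
Log2 fold changes against WT (y axis) of genes along chromosomes III and IX (x axis, position in kb of build R64), in dgk1Δ (top, blue) and pah1Δ (bottom, red); shading marks the segments, the dotted line the centromere and the dashed line a log2 of 1. Genes of the segments have medians of 1.03 and 0.92 in dgk1Δ and of -0.02 and 0.01 in pah1Δ.

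Outside the segments 17 genes were higher and 17 lower in dgk1Δ. Chosen after their values were seen, YDR098C-B (2.23, edgeR adjusted p = 9.79e-06) and YFL067W (1.84) rose more than any tested segment gene. Neither has a standard symbol, so the rule for named genes left them out. Named after their values were seen, the higher ones included IMD2, an IMP dehydrogenase (1.03), and its near-identical relative IMD1 (1.35), the receptor STE3 (1.02, overlapping YKL177W), the glutamine permease GNP1 (0.96, overlapping YDR509W) and the glycerol-3-phosphate dehydrogenase GPD1 (0.47). The lower ones included the neighbours ARR2 (-2.48) and ARR3 (-1.58), which lie beside ARR1 near the right end of chromosome XVI. With the segment genes left out of the fit, 8 genes were higher and 14 lower. Leaving them out does not separate the loss of DGK1 from effects of the segments on other genes, since every dgk1Δ library had both. Of 24 genes of the unfolded protein response 2 rose, also when adjusted over the list alone, the disulfide isomerases PDI1 (1.04, overlapping YCL041C) and EPS1 (1.00), with KAR2 at 0.26 and LHS1 at 0.14. Both that rose are segment genes, and the list's call (camera adjusted p = 0.0196) ended without segment genes (0.243) and with an estimated correlation (adjusted p = 0.528 with an estimated correlation). It also ended without WT replicate 3 or dgk1Δ replicate 3 (adjusted p 0.0939 and 0.0667; median 0.03 without WT replicate 3).

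Camera called none of the remaining 21 lists in dgk1Δ, and edgeR few of their members. Some were called under an alternative: the tricarboxylic acid cycle without segment genes (0.022), without WT replicate 1 (0.048) and with fry (0.0371), and the nuclear pore without WT replicate 1 (0.048). Others were fatty acid synthesis with the length trend removed (0.0147), MATalpha-specific and stationary-phase genes with fry (0.00115 and 0.0366), respiration without WT replicate 3, and the iron regulon without dgk1Δ replicate 2. In fatty acid synthesis MGA2 and FAA3 (0.75) rose, and among Gcn4 targets HIS4 (1.06) and LYS1 (0.84), all 4 on the segments. The iron gene HMX1 fell by 0.46 but lost its call without WT replicate 3 or any dgk1Δ library (adjusted p 0.115 to 0.239), with library size only, only the 2 groups, a replicate block and limma-voom, and STE3 rose among MATalpha-specific genes, with MF(ALPHA)2 at -0.12. Other members with the smallest adjusted p did not pass edgeR's test over all genes: ICT1 (0.24) and NEM1 (-0.23) of neutral lipid metabolism, MVD1 (-0.22) and ERG10 (0.14) of ergosterol synthesis, YPC1 (0.24) and ISC1 (0.13) of sphingolipid metabolism, CTA1 (-0.26) and ANT1 (-0.19) of beta-oxidation, and CYC7 (1.52, SE 0.586) and COX5A (-0.26) of respiration. The same held for CIT1 (0.31) and IDH1 (0.18) of the tricarboxylic acid cycle, PHM7 (0.65) and PHM8 (0.42) of the phosphate regulon, ZPS1 (-0.54) and ADH4 (-0.52) of the zinc regulon, ARN1 (-0.43) of the iron regulon, PRM5 (0.55) and CWP1 (0.49) of cell wall integrity, and PDC5 (-0.40) and CDC19 (0.15, overlapping YAL037C-B) of glycolysis. It also held for GAL2 (0.40) and HXT5 (0.29) among glucose-repressed genes, NUP120 (-0.08) and GLE2 (-0.08, overlapping YER107W-A) of the nuclear pore, ATG11 (0.25) and ATG19 (0.20) of autophagy, CDC21 (0.19, overlapping YOR073W-A) and TOS4 (0.13) of S phase, MFA1 (-0.57) and MFA2 (-0.35) among MATa-specific genes, SPR28 (0.55) and SPS4 (-0.31) of meiosis, and RTC3 (0.45) and PHM7 of stationary phase. DESeq2 called 1 member each of the phosphate, cell wall integrity, MATa-specific and stationary-phase lists, and limma-voom 0. Adjusted over the list alone, 2 phosphate genes were higher, and 2 iron genes and 1 MATa-specific gene lower. The Gcn4 list had a median of -0.02 but a mean of 0.02 and an upward camera direction.

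Pah1Δ and dgk1Δ were then compared directly. INO1 was higher in pah1Δ by 4.75 (log2, SE 0.484, edgeR adjusted p = 4.55e-05), YGP1 by 3.55, TMA10 by 3.40, TIS11 by 3.32 and PIR3 by 3.09, and ZPS1 (-3.90), ZRT1 (-2.74), ADH4 (-2.34), GNP1 (-2.28, overlapping YDR509W) and the segment gene FUS1 (-1.82) were lower. Of the 19 genes with an inositol-responsive element 10 were higher and 1, PCT1, lower (11 and 1 adjusted over the list alone), median 0.36. PCT1 lost its call without pah1Δ replicate 1 or any dgk1Δ library (adjusted p 0.0529 to 0.0672), with library size only and on log2(FPKM + 0.1). Of the higher genes, CDS1 and CKI1 lost theirs without pah1Δ replicate 1 or 3 or dgk1Δ replicate 2 or 3 (0.0825 to 0.119 and 0.0581 to 0.0817), and EPT1 without dgk1Δ replicate 2 or 3 (0.0586 and 0.0529). After INO1 came OPI3 (1.57), ITR1 (0.90), PSD1 (0.81, overlapping YNL170W) and INO4 (0.72), then CHO1 and CHO2 (both 0.69). Camera called this list (adjusted p = 0.000586), and the call was lost with an estimated correlation (adjusted p = 0.317 with an estimated correlation). General stress (32 of 37 higher, median 1.10), stationary-phase (11 of 16, 1.06), cell wall integrity (16 of 21, 1.13) and beta-oxidation genes (12 of 20, 0.62) were called with an estimated correlation too (adjusted p = 0.00265, 0.00265, 0.0317 and 0.00836 with an estimated correlation). Adjusted over the list alone, 33, 13, 16 and 13 of their members were higher. Of 30 methionine and sulfur assimilation genes 8 were higher and 6 lower (9 and 8 adjusted over the list alone), median 0.01, and the list was not called (0.775): MUP1 (1.13), STR3 (0.85), MHT1 (0.62) and SAM3 (0.55) were higher, and MET16 (-0.62) and MET14 (-0.47) lower. Ribosomal protein (49 of 138 lower, 1 higher, median -0.33), ribosome biogenesis (35 of 52 lower, -0.29) and zinc genes (9 of 15 lower, -0.61) were called by camera, not with an estimated correlation (adjusted p = 0.59, 0.126 and 0.132 with an estimated correlation), and the first not with fry (0.0715). Adjusted over the list alone, 58, 38 and 10 were lower and 1, 0 and 2 higher. In all, 876 genes were higher and 666 lower, with library size only 1081 and 437, and on log2(FPKM + 1) 1058 and 438 (higher share 56.8%, 71.2% and 70.7%). The lower calls numbered 382 without pah1Δ replicate 1 and 413, 406 and 379 without dgk1Δ replicates 1, 2 and 3. Segment genes, which were higher in dgk1Δ, add to the lower calls here. With them left out of the fit, 866 genes were higher and 567 lower.

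The calls of both deletions against WT overlapped in 49 genes, of which 28 were higher in both, 5 lower in both, 15 lower in pah1Δ and higher in dgk1Δ, and 1, HMX1, the reverse. Independent lists of the same sizes would share 16.8, 2.14, 12.7 and 2.83 genes. Outside the segments the numbers were 10, 5, 2 and 1, against 2.82, 2.14, 2.14 and 2.82. With the segment genes left out of the fit, 9 genes were called in both deletions, 8 of them in the same direction. Both comparisons used the same WT libraries, whose error moves both fold changes alike. Independent lists therefore set the expected overlap too low for the same direction and too high for opposite ones. The 10 included HXK1 (2.63 in pah1Δ, 0.81 in dgk1Δ), HSP42, PNC1 (1.57 and 0.61), GPD1 (1.28 and 0.47) and STE3, and the 5 lower in both were SAM3, OPT1, NIT1, MMP1 and TPN1. GNP1 fell by 1.32 in pah1Δ and rose by 0.96 in dgk1Δ. Across genes, which are not independent replicates, the fold changes correlated with r = 0.302, against a mean of 0.506 for simulated unchanged groups that share the WT libraries. The covariance was 0.0415, against a simulated 0.0154 and against 0.0269 from the measured WT variance divided by 3, and 65.9% of genes had the same sign against 66.7%. The simulated groups held no real changes, so shared WT error sets their r and sign share. Real changes in a single deletion lower both. The r and sign share therefore do not show whether the deletions agree more or less than such groups. The overlap was 99 genes without WT replicate 1, 29 without WT replicate 3 and 27 without pah1Δ replicate 1.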

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

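The fits with the length trend removed, without segment genes and without WT replicate 1 and pah1Δ replicate 2 together, and the KEGG tests, were chosen after the results were seen. No named gene or list that passed the threshold changed direction past it under any alternative run, so no call reversed.

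Over all alternatives, named genes in pah1Δ against WT kept their direction and side of the threshold in 2210 values, lost a call in 50 and gained one in 13; for dgk1Δ against WT the numbers were 1767, 26 and 38, and for pah1Δ against dgk1Δ 3170, 97 and 57. In pah1Δ against WT, 1023 higher and 775 lower calls became 259 and 25 with a fold of at least 2, and 658 and 380 at an adjusted p under 0.01. The lower calls were 480 with library size only, 485 with only the 2 groups compared, 462 and 464 on log2(FPKM + 1) and log2(FPKM + 0.1), 1316 with both libraries out, and 447 (pah1Δ replicate 1) to 1172 (WT replicate 1) leaving out 1 library. In dgk1Δ against WT, 101 higher calls, of which 84 lay in the segments and 17 outside, became 8 without segment genes, and 48 with a fold of at least 2. The 17 lower calls became 30 with the length trend removed, 38 with DESeq2 and 6 with a fold of at least 2. In pah1Δ against dgk1Δ, 876 higher and 666 lower calls became 200 and 69 with a fold of at least 2, and 534 and 324 at an adjusted p under 0.01. Without segment genes they were 866 and 567. The lower calls were 437 with library size only, 1010 with only the 2 groups, 438 and 435 on FPKM, and 379 (dgk1Δ replicate 3) to 569 (pah1Δ replicate 2) leaving out 1 library.

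Camera called 22, 9 and 18 lists in the 3 contrasts and 5, 0 and 4 with an estimated correlation. Of the KEGG pathways it called 28 for pah1Δ against WT, 19 for pah1Δ against dgk1Δ and 8 for dgk1Δ against WT outside the segments, and 0 with an estimated correlation. Segment genes were included in the tests that gave the 28 and the 19. The 49 genes called in both deletions became 26 with only the 2 groups, 96 with the length trend removed, 81 with DESeq2, 9 without segment genes, 4 with a fold of at least 2, 24 at an adjusted p under 0.01, and 27 (pah1Δ replicate 1) to 99 (WT replicate 1) leaving out 1 library. Where not stated, the cause was not tested. The replicate block assumed that equal numbers pair samples, which the labels do not say. At this depth, simulated changes of 0.5 (log2) were recovered in 58.2%, 62.1% and 45.5% of genes in the 3 contrasts. The simulated libraries held no trend by gene length and none that stood apart, so recovery in the measured libraries may be lower.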

Other observations

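The length test of the stress genes was set before its result was seen. So were the tests of chromosome ends without stress lists and without repeated families. The other tests below, the KEGG tests and the counts of other splits included, were chosen after the result was seen. Bootstrap intervals below are over genes, which are not independent replicates, and do not cover the spread between libraries.

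In pah1Δ, genes of KEGG starch and sucrose metabolism were higher (24 higher and 2 lower of 43, median log2 fold change 0.45, camera adjusted p = 6.67e-09, adjusted p = 0.0574 with an estimated correlation). Chosen after their values were seen, GPH1, the glycogen phosphorylase, rose by 2.01, TSL1, of the trehalose synthase complex, by 1.75 and the debranching enzyme GDB1 by 0.99. Among lysine biosynthesis genes 9 of 12 fell, with LYS2 at -0.47 and LYS20 at -0.45 (camera adjusted p = 0.000345, adjusted p = 0.284 with an estimated correlation).

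The segments of chromosomes III and IX were higher in each dgk1Δ library and not in WT or pah1Δ. A depth or normalization effect would move genes of like expression alike. Within each dgk1Δ library the segment medians lay at least 0.843 (bootstrap interval 0.81 to 0.976) above those of such genes elsewhere. The segments had been picked for lying above other genes, so this gap was largely set by the choice. It is no independent test of that explanation. The 102 tested genes of the 2 segments all had fold changes above 0, and 84 were called. The choice of the segments favoured these counts too, so they are no separate support. Each shuffle of gene order was searched for its largest run in the same way, and 0 of 100 gave a run as large. This was also required for a run to be called. It argues against genes that change one by one without regard to their place. An extra copy of both segments may explain the pattern: the lowest of the 6 library medians was 0.864, near the log2 of 1 that a doubled copy in a haploid would give. Both runs reached the outermost gene scanned on their side, so their outer ends were set by the scan. Beyond the chromosome IX run, YIR043C (0.77) and YIR044C (0.58) also had fold changes above 0 in dgk1Δ, but neither passed edgeR's test. At the inner edge of each segment the annotation has a tRNA gene and long terminal repeats of Ty elements, whose role was not tested. Regulation of whole regions stays open and was not tested, no DNA reads were analysed here, and the ploidy is not given.

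Stress genes were higher and ribosomal protein genes lower in pah1Δ, while WT replicate 1 and pah1Δ replicate 2 stood apart with a trend by gene length. With the length trend removed the stress median was 1.567 (bootstrap interval over genes 1.108 to 1.743). The ribosomal protein median was -0.381 (-0.401 to -0.365). That both medians remained argues against that trend as the whole cause. Without both libraries the medians were 1.546 (0.991 to 1.713) and -0.359 (-0.383 to -0.343), against 1.51 and -0.437 with them, which argues against these libraries as the whole cause. Without WT replicate 1 alone the ribosomal protein median was -0.284, so part of its size rests on that library. Single libraries spread more widely than the intervals. Their ribosomal protein medians ran from -0.28 to 0.44 in WT and from -0.54 to -0.25 in pah1Δ. The loss of PAH1, slower growth or another state of the cultures could each give this pattern, and none of these was tested apart.

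Of 332 genes within 30 kb of a chromosome end, 87 were higher and 31 lower in pah1Δ, with a median of 0.169 (bootstrap interval 0.12 to 0.245), above 0.095, the upper limit of the central 95% of medians of random gene sets matched on expression. Without repeated end families and genes with no symbol it was 0.12 (0.096 to 0.17; upper limit 0.077), which argues against shared reads as the whole cause. Only 5 of the 332 are on the stress, stationary-phase or glucose-repressed lists, so the median of 0.164 without them decides nothing, and stress genes outside these lists stay open. An effect of position may contribute, as a hypothesis. In dgk1Δ, without segment genes, the median near ends was 0.047 (0.011 to 0.07; upper limit 0.036), which leaves open whether the same holds there.

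Each contrast of 3 against 3 libraries has 10 splits, so no share under 0.05 can be reached, and 1 of the 10, the real one, called as many genes in each contrast. The real splits called 1798 (pah1Δ against WT), 118 (dgk1Δ against WT) and 1542 genes (pah1Δ against dgk1Δ), and the highest other split 0 in each. Every other split mixes both genotypes within each group, so real differences widen the spread it is tested against. Its 0 calls therefore do not show what chance alone would give. At an unadjusted p under 0.05 the real splits gave 2469, 548 and 2247 genes and the highest other 1381, 884 and 200. For dgk1Δ against WT another split exceeded the real one there, which points to a structure of the samples other than genotype. That split set WT replicate 1 and dgk1Δ replicates 1 and 3, whose deviations fell with gene length (correlations -0.745, -0.138 and -0.429), against the other 3 (0.693, 0.605 and 0.537). With the length trend removed the real contrast called 160 genes.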
